A study of Saccharomyces cerevisiae with 50 samples.

How the data were processed

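The series followed gene expression through the cell cycle of a budding yeast strain (Saccharomyces cerevisiae) that lacks YOX1. Cells were held in G1 with the mating pheromone alpha factor, released into rich medium and sampled over 120 min. RNA of each time point was labelled with Cy5 and hybridised together with Cy3-labelled RNA of an asynchronous wild-type culture, per the labels. There are 50 arrays, 2 for each of 25 time points 5 min apart. The titles place the arrays in 2 sets with 1 array per time point in each, and the design text calls the repeats technical. In array set 2, the arrays of 0, 5 and 15 min carry the letter M in their titles, where all other titles share a number. The meaning of the letter is not stated, so the titles leave open whether these samples come from the same culture. All arrays were treated as 1 time course on the word of the design text. P-values measure the scatter of time points around a fitted course, not the spread between cultures. The treatment protocol in the labels gives a sampling interval of 10 min, against 5 min in the design text and the time points themselves. One array is named 75 min in its title and 0 min in its source name; it was counted as 75 min, and left out in an alternative.

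The values deposited by the authors are log10 ratios of the time point over the reference. The base is inferred from the values and not stated: they end at exactly -2 and 2, that is a ratio of 100 either way, with 212 values of open reading frames on the limits (171 at the lower and 41 at the upper) and 4 between 1.9 and 2 in size. The direction, Cy5 over Cy3, follows from the dyes in the labels together with the high ratio of the pheromone-induced FUS1 at 0 min, and is likewise not stated for the values. All log2 sizes below depend on that base. Scanner, background correction, normalization and spot filters are not given in the sources used here. The array medians lay between -0.000700 and 0.0478 on the deposited log10 scale. Arrays held values for 5528 to 6110 of the 6205 open reading frames, and 4.34% of values were missing. No intensities were used here, so the signal behind a ratio is unknown, and the number of arrays limits the precision.

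Of 6217 rows, 12 control rows were left out. Names were taken from a table of assembly R64, which matched 5704 open reading frames by locus tag; the other 501 kept the name in the file. The file names no genome build, so no coordinates are given. Values on the limits were set to missing, ratios were converted to log2, each array was centred on its median, and the 2 arrays of a time point were averaged. Genes measured at 20 or more of the 25 time points were tested, which left 6063.

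Tests used limma 3.58.1 in R 4.3.3; figures used matplotlib 3.10.9 in Python 3.11.15. The period was the value between 40 and 90 min, in steps of 1 min, with the smallest residual variance over 80 marker genes. These were the measured members of the MBF, SBF, histone, CLB2 and SIC1 lists described below. Periodic genes were called by a moderated F-test of cosine and sine terms at that period, beside a linear time term, at a Benjamini-Hochberg adjusted p under 0.01. The peak-to-trough size is the full height of the fitted wave. Release from alpha factor was tested as an added term for 0, 5 and 10 min, so that it measures the departure of these samples from the fitted cycle. The mean over the course was tested against a fold change of 1.5 with treat. Gene lists were compared with camera at a preset correlation of 0.01 and again with an estimated one, on the 5777 genes measured at every time point; the share of periodic genes was compared with Fisher's exact test. Peak times of lists were compared by two-sided permutation of the circular mean difference, exact where fewer than 100000 arrangements exist. No array has the dyes exchanged, so a dye bias of single genes is not separated from the mean ratio, and the reference counts as 1 control sample whose own spread is not included.

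The tests, the 16 gene lists and the rule for named genes were fixed before the data were examined. The rule takes YOX1, YHP1 and MCM1; the 20 periodic genes of largest peak-to-trough size whose peak times in the 2 array sets differ by 10 min or less; the 10 highest and the 10 lowest genes past the threshold, with the same sign in both sets, for release and for the mean; and of every list the 4 members with the largest effect, plus any member behind a count of 5 or fewer. Another 5 lists were written after the data were seen and are used only in the closing section. Alternatives covered each array set alone, centring, scaling, the filter on missing time points, the period, the form of the time trend, array set or title date as a factor, each time point left out and other thresholds.

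The scripts were tested on simulated data for 6063 genes. Of genes simulated with a peak-to-trough size of 1 and 2 on the log2 scale, 79% and 94% were called periodic, with 2 false calls. A release effect of 1 and 2 was recovered in 70% and 87% of genes with 1 false call, and a mean of 1 and 2 in 89% and 100% with 0 false calls. False periodic and release calls were counted only among genes simulated with neither effect, so a release effect called periodic, or the reverse, is not included. Simulated waves were cosines of constant height at the period used in the fit, so damped or missing waves were not tested. Noise in the simulation was independent between time points, so it does not test slow drifts.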

Results

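Expression was measured in a yox1 deletion strain at 25 times from 0 to 120 min after release from alpha factor, with 2 arrays per time point, each against asynchronous wild-type RNA. Yox1 is a homeodomain repressor that acts with Mcm1 at early cell cycle box (ECB) promoters, which are active around the M/G1 transition, and Yhp1 is its close relative. No wild-type time course was analysed here, so the timing of each gene group is given for the mutant alone. Sizes are log2 ratios, on the inferred assumption that the deposited values are log10 ratios of the mutant over the reference.

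The deleted gene was looked at first. The YOX1 probe lay below the reference on 49 of 49 arrays that measured it, between -2.25 and -0.02. Its mean over the course was -1.12 ± 0.07 (SE, 25 time points), 2.17-fold lower than in the reference, with a limma adjusted p of 8.93e-07 against a fold change of 1.5. The mean was -1.26 ± 0.38 (SD, n = 25) in array set 1 and -0.92 ± 0.44 (SD, n = 24) in array set 2. Against a fold change of 2 the call was lost, and 109 genes had a lower mean, so the probe kept part of the reference signal in the deletion strain. YOX1, itself a G1 gene in wild-type cells, was not called periodic (adjusted p = 0.067). The position of the probe relative to the deleted part is not known here. YHP1 had a mean of 0.05 ± 0.04 and MCM1 of -0.66 ± 0.05; neither passed the test of the mean, the release test or the test for periodicity, but YHP1 was called periodic without 25, 40 and 55 min (adjusted p = 0.000398 against 0.0682).

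**Figure D1:**
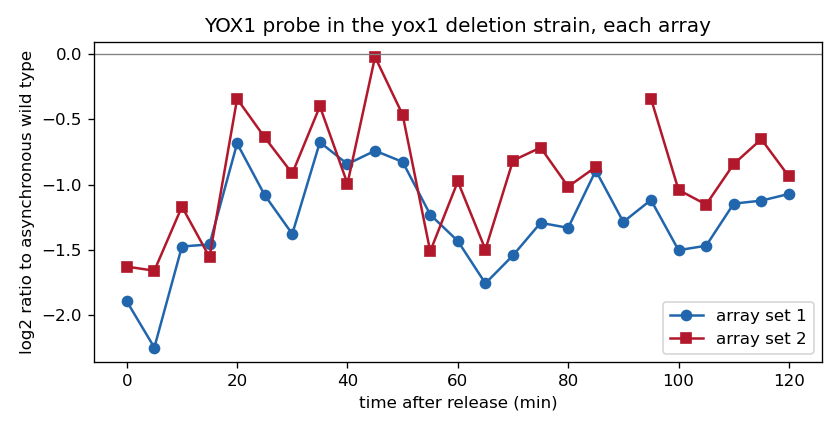
Log2 ratio of the YOX1 probe (vertical axis) against time after release in min (horizontal axis), 1 point per array, with array set 1 as circles and array set 2 as squares. All 49 measured points lie below 0.

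The arrays of a time point were compared next. Across genes, which are not independent replicates, Pearson's r between the 2 arrays had a median of 0.716 over the 25 time points. Over time, the profile of a gene in one set correlated with that in the other with a median r of 0.812 for 802 periodic genes and 0.627 for 4903 other genes. The samples of 25, 40 and 55 min stood apart in both sets. The SD of log2 ratios over genes on their 6 arrays was 0.74 to 1.23, against 0.33 to 0.83 on the other 44 arrays. Total counts below, and list counts that moved, are therefore also given without these 3 time points, an alternative chosen after seeing the data.

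**Figure D2:**
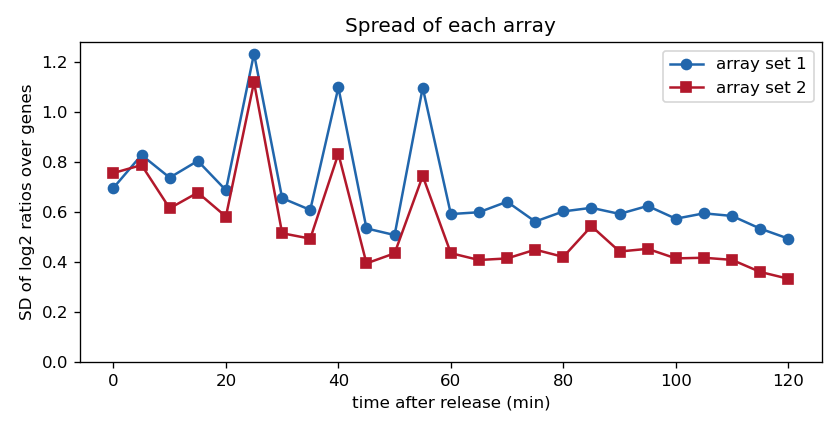
SD over genes of the log2 ratios of each array (vertical axis) against time after release in min (horizontal axis), for array set 1 (circles) and array set 2 (squares). Both sets have peaks at 25, 40 and 55 min, with SDs of 1.23, 1.10 and 1.10 in set 1 and 1.12, 0.83 and 0.74 in set 2.

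Cell cycle genes oscillated with a period of 71 min, the same in each array set alone. Of 6063 genes tested, 805 (13.3%) were periodic, with a median peak-to-trough size of 0.68 and quartiles of 0.52 and 1.02. Several histone genes, which encode chromatin proteins made in S phase, were among the widest swings: HHF2 reached 3.04 ± 0.46 (SE), HHF1 3.03 ± 0.48, HTA2 2.96 ± 0.40, HTA1 2.89 ± 0.38, HTB2 2.84 and HTB1 2.74, all with peaks from 34.2 to 35.7 min. HHT1 (2.24), HHT2 (2.09) and HHO1 (1.44) swung less. Histones lay a median of 0.92 above neighbouring times at 25, 40 and 55 min, which raises their peak. Copies of a histone are near-identical, so a probe may read both. Also among the 20 largest were the daughter cell separation genes EGT2 (2.96 ± 0.32, fitted peak at 6.70 min), DSE4 (2.74 ± 0.37) and DSE3 (2.39 ± 0.26). So were the cell wall genes NCW2 (2.76 ± 0.28), PIR1 (2.53 ± 0.34), PST1 (2.43 ± 0.29) and HSP150 (2.41 ± 0.58). HO, which encodes the mating-type endonuclease, swung by 2.64 ± 0.26 and peaked at 13.7 min. RNR1, the large subunit of ribonucleotide reductase, swung by 2.56 ± 0.44, the cohesin subunit MCD1 by 2.49 ± 0.38 and the anaphase regulator ACM1 by 5.64-fold. TOS6, SVS1 and MRH1 swung by 2.51 ± 0.53, 2.43 ± 0.46 and 2.40 ± 0.45.

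Most members of the G1 to M lists were periodic. The list of MBF targets, DNA replication genes of late G1, had 19 of 21 periodic members (21 adjusted over the list alone), among them RNR1, MCD1, POL30 (2.14 ± 0.36) and CDC21 (2.08 ± 0.24). Of the SBF targets, late G1 genes of budding and cell wall growth, 7 of 12 were periodic (8 adjusted over the list alone), with SVS1, PCL1 (2.33 ± 0.43), the G1 cyclin CLN2 (2.26 ± 0.26) and MNN1 (1.95 ± 0.17) at the top. Histones had 8 of 9 (9 adjusted over the list alone) and the S/G2 list 9 of 10 (10), with CIN8 at 1.18 ± 0.17 and SLK19 at 1.07 ± 0.14. The CLB2 cluster of G2/M genes had 15 of 19 (17), with CHS2 at 2.20 ± 0.33, HOF1 at 2.14 ± 0.30, the polo kinase CDC5 at 1.66 ± 0.21 and ALK1 at 1.64 ± 0.16. The SIC1 cluster, expressed as cells leave mitosis, had 12 of 19 (15), and its chitinase gene CTS1 had a size of 0.10 ± 0.09. Fisher's exact test gave adjusted p-values of 4.68e-14 for MBF, 1.15e-09 for CLB2, 5.80e-07 for S/G2, 2.29e-06 for SIC1, 2.38e-06 for histones and 0.000816 for SBF. Except for S/G2, the period was fitted on the members of these lists, so their shares are not independent of that choice. Without 25, 40 and 55 min the periodic members numbered 20 for MBF, 9 for SBF, 9 for histones, 10 for S/G2, 15 for CLB2 and 12 for SIC1. Of the ECB list, 5 of 12 genes were periodic (6 adjusted over the list alone; adjusted p = 0.0257, over the threshold of 0.01, and 0.253 without 25, 40 and 55 min): the G1 cyclin CLN3 (1.13 ± 0.26), the cyclin kinase inhibitor FAR1 (1.89 ± 0.40), TEC1 (1.15 ± 0.24), MCM2 (0.57 ± 0.13) and MCM5 (0.65 ± 0.15). SWI4 (0.82 ± 0.25, adjusted p = 0.0508) and CDC6 (0.50 ± 0.28, adjusted p = 0.408), both with known ECB elements, were not called.

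Outside the cell cycle lists, 8 of 16 stress genes were periodic (10 adjusted over the list alone; 11 without 25, 40 and 55 min; Fisher's exact test, adjusted p = 0.00102), with the trehalose and glycogen genes TSL1 (1.55 ± 0.13), GPH1 (1.38 ± 0.21), PGM2 (1.34 ± 0.21) and the glycerol gene GPD1 (1.21 ± 0.22) leading. Ribosomal protein genes had 6 periodic of 137 (3 adjusted over the list alone), fewer than other genes (adjusted p = 0.00162), but 38 of 137 without 25, 40 and 55 min, where that difference was lost (adjusted p = 0.583). Ribosome biogenesis had 5 of 15 (7 adjusted over the list alone): NUG1, NSR1, NOP2, MAK16 and GAR1, with sizes from 0.64 to 0.80; without the 3 time points it had 12 of 15 (adjusted p = 3.97e-05). Respiration had 3 of 14 (4): SDH2, SDH1 and CIT1, and 9 of 14 without the 3 time points (adjusted p = 0.00387). The phosphate list had 3 of 12 (5): PHO5, SPL2 and PHO84, and 4 of 12 without the 3 time points. In the pheromone list GPA1 alone of 25 was called (0 adjusted over the list alone), in the strain markers HO alone of 9 (3), and the methionine and alpha-cell lists had 0 of 11 and 0 of 3 by limma. The strain markers had 3 of 9 without the 3 time points. Without 25, 40 and 55 min, 1526 genes were periodic, including 765 of the 805. Within single title dates the count was 29 over 13 time points, 223 over 12, 549 over 14 and 0 over 8. Of these, 29, 178, 296 and 0 were among the 805 of the full course. The date with 0 calls had 62 of 5543 genes at an unadjusted limma p under 0.05, fewer than chance alone would give. Date is largely tied to the part of the course.

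**Figure D3:**
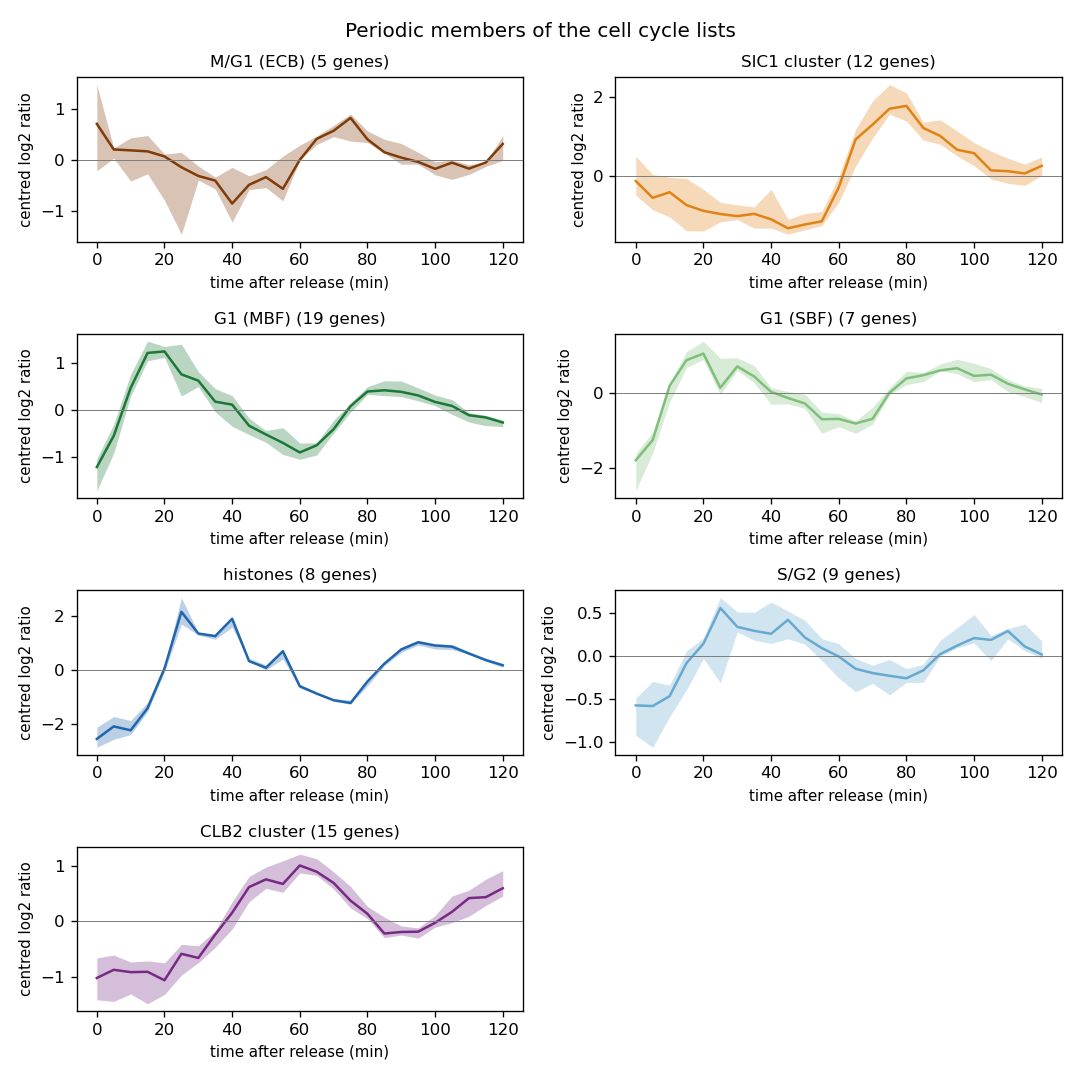
Median log2 ratio, each gene centred on its own mean (vertical axes), against time after release in min (horizontal axes) for the periodic members of 7 lists, with the quartiles over genes shaded. Histones and the MBF and SBF lists rise early and again, lower, after 71 min, and the SIC1 cluster is highest after 60 min.

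The order of peak times in the mutant ran from the ECB list to the CLB2 cluster. The circular mean peak lay at 2.84 min for the 5 periodic ECB genes (SD 3.38), 7.17 min for the SIC1 cluster (SD 3.46, n = 12), 22.8 min for MBF (SD 2.52, n = 19), 25.6 min for SBF (SD 2.83, n = 7), 34.5 min for histones (SD 0.838, n = 8), 37.8 min for S/G2 (SD 5.46, n = 9) and 56.6 min for the CLB2 cluster (SD 3.47, n = 15). Fitted times are folded into 1 period. With each gene centred on its own mean, the median of the periodic SIC1 genes was -0.57 at 5 min and -0.42 at 10 min. It was 1.70 at 75 min and 1.78 at 80 min. The SIC1 time thus stems from the wave about 1 period later, and the median showed no peak near 7.17 min itself. Permutation over genes, which are not independent replicates, was run on 7 pairs of lists. MBF preceded histones by 11.7 min, S/G2 preceded CLB2 by 18.8 min and CLB2 preceded SIC1 by 21.6 min, each with a permutation p of 1e-05, the smallest that can be reached, and an adjusted p of 2.33e-05. ECB preceded SBF by 22.7 min (exact permutation p = 0.00126, adjusted 0.00221). The ECB time rests on the 5 called members of 12. Uncalled members were spread, with fitted peaks at 20.3 min for SWI4 and 18.7 min for CDC6, but 5.08 min for MCM4 and 70.7 min for STE6. The ECB mean minus that of the SIC1 cluster was -4.33 min and the MBF mean minus that of SBF -2.72 min (exact permutation p = 0.0388 and permutation p = 0.0335, both adjusted to 0.0453). Histones and S/G2 genes were 3.36 min apart (exact permutation p = 0.118). Of the 7 pairs, 6 passed at an adjusted p under 0.05, against 5 with either array set alone or scaled arrays, 4 with all measured members and 7 without 25, 40 and 55 min.

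**Figure D4:**
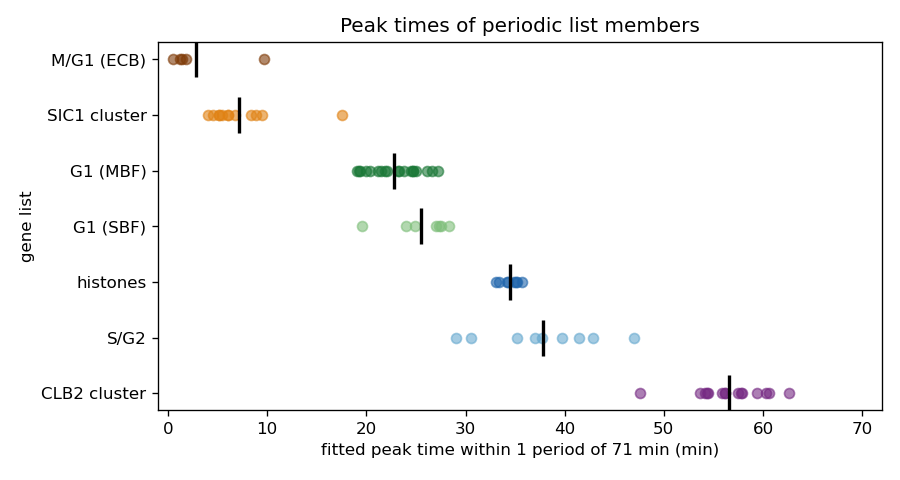
Fitted peak time in min within 1 period of 71 min (horizontal axis) of each periodic list member (points), by gene list (vertical axis); black bars are circular means. ECB genes average 2.84 min and CLB2 cluster genes 56.6 min.

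The second cycle was smaller for most genes. The fitted amplitude over 60 to 120 min was a median of 0.567 of that over 0 to 60 min for 805 periodic genes (quartiles 0.457 and 0.726), and 708 of them were below 1. The median was 0.575 in array set 1 and 0.567 in array set 2. By list it was 0.512 for histones, 0.537 for MBF, 0.583 for ECB, 0.584 for S/G2, 0.593 for SBF and 0.638 for CLB2. Medians over 1 were found for the SIC1 cluster (1.72) and the 3 periodic phosphate genes (2.82), and HO had a ratio of 6.11. The centred median of the periodic SIC1 genes lay below 0 from 0 to 60 min and peaked at 80 min (1.78), so their ratio does not compare 2 waves. With all arrays scaled to the same spread the median over genes was 0.767.

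At release, 13 of 25 pheromone genes stood above the cycle model and 7 of 19 genes of the CLB2 cluster below it. At 0, 5 and 10 min, 80 genes were higher and 77 lower than the cycle model gave for that phase. The agglutinin AGA1 was higher by 4.46 ± 0.44 (SE, adjusted p = 1.44e-06), with its mean of both arrays at 5.45 at 0 min and -0.51 at 20 min. The separation gene DSE2 was higher by 4.06 ± 0.54 but by only 0.20 against 70, 75 and 80 min (adjusted p = 0.881), where AGA1 was higher by 4.85. Also higher were the fusion gene FIG1 by 3.48 ± 0.38, the alpha factor protease BAR1 by 3.22 ± 0.50, the a-factor gene MFA1 by 3.17 ± 0.64, ASG7 by 3.07 ± 0.33, PRM1 by 3.06 ± 0.57, FIG2 by 2.82 ± 0.28, the desensitisation regulator SST2 by 2.67 ± 0.41 and AGA2 by 6.08-fold. In the pheromone list 13 of 25 genes lay above the model and 0 below it (20 and 0 adjusted over the list alone), with a camera adjusted p of 5.13e-27; the call was lost with an estimated correlation (adjusted p = 0.0291). FUS1 reached 3.82 at 0 min and was 0.57 at 5 min, and its release term of 2.02 ± 0.56 did not pass (adjusted p = 0.0309).

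Genes below the model at release included YOR248W, 7.84-fold lower (adjusted p = 7.27e-06), TOS6 (6.46-fold), SVS1 (-2.36 ± 0.41), the sirtuin HST3 (3.99-fold), CIS3 (3.76-fold), HTA2 (-1.85 ± 0.42), TOS4 (-1.74 ± 0.27), MCD1 (-1.70 ± 0.40), the iron mannoprotein FIT2 (3.38-fold, but only -0.71 on the log2 scale against 70, 75 and 80 min) and RAX2 (3.05-fold). In the CLB2 cluster 7 of 19 lay below the model and 0 above it (13 and 0 adjusted over the list alone), with HST3, HOF1 and CLB1 among them; camera gave an adjusted p of 3.59e-15, and the call was lost with an estimated correlation (adjusted p = 0.0291). In the S/G2 list 2 of 10 lay below it, STU2 and CIN8 (4 adjusted over the list alone), and the camera adjusted p of 4.02e-06 became adjusted p = 0.00109 with an estimated correlation. In MBF 4 of 21 lay below it (TOS4, MCD1, CDC21 and SMC3; 10 adjusted over the list alone), in SBF 3 of 12 (SVS1, SWE1 and CLN1; 5) and among histones 1 of 9 (HTA2; 8). Their camera adjusted p-values of 6.05e-12, 3.91e-06 and 3.30e-09 were lost with an estimated correlation, as adjusted p = 0.129, 0.144 and 0.0638. The cycle model has a constant wave height, but the second cycle was smaller in these cell cycle lists. Median ratios to the first cycle were 0.512 for histones, 0.537 for MBF, 0.584 for S/G2, 0.593 for SBF and 0.638 for CLB2. A wave that is larger in its first cycle can put genes that are low at release below the model. For these lists a release effect is thus not separated from damping. Ribosome biogenesis (0 of 15 called, adjusted p = 0.00138) and the phosphate list (0 of 12, adjusted p = 0.00701) also passed camera, higher and lower, and were lost with an estimated correlation (adjusted p = 0.241 and 0.144). In the SIC1 cluster DSE2 and DSE1 were above the model of 19, though DSE1 was at -0.57 against 70, 75 and 80 min (adjusted p = 0.633). In that comparison DSE2 was at 0.20, but EGT2 was at -3.69, PCL9 at -3.31 and DSE3 at -2.56 (limma adjusted p = 0.00419, 0.000784 and 0.00428). The release terms of EGT2, PCL9 and DSE3 did not pass (limma adjusted p = 0.836, 0.0330 and 0.995), so the model missed their low values at release. In the ECB list MCM2 was below the model of 12, in the stress list GPH1 was above the model of 16 and among strain markers BAR1 of 9. Against 70, 75 and 80 min GPH1 was higher by only 0.10 (adjusted p = 0.842) and BAR1 by 1.63 (adjusted p = 0.225). None of these lists passed camera. Of the methionine, ribosomal protein, respiration and alpha-cell lists 0 genes passed limma's test. Without 25, 40 and 55 min, 221 genes were higher and 244 lower, including 80 and 76 of those called. Below the model were then 10 genes of the CLB2 cluster, 5 each of SBF and S/G2, 4 each of MBF and histones and 3 of ECB. So were 2 each of the SIC1, phosphate and respiration lists and 1 of the methionine list. Above the model were 14 of the pheromone list, 3 of SIC1 and 1 each of the ECB, ribosomal protein, stress and strain marker lists. The counts were 46 and 34 without 5 min, 49 and 35 without 0 min, and 46 and 47 with 2 harmonics in the model. Against 70, 75 and 80 min, about 1 period later, 77 of the 80 and 76 of the 77 kept their sign, but only 8 and 13 of them passed on these 6 time points.

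**Figure D5:**
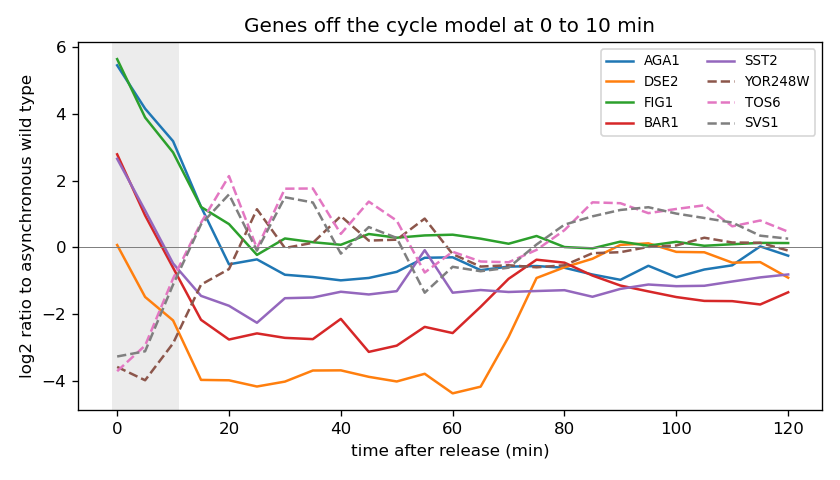
Log2 ratio, mean of both arrays (vertical axis), against time after release in min (horizontal axis) for 5 genes above the cycle model at 0 to 10 min (solid) and 3 below it (dashed); the shaded span marks 0 to 10 min. AGA1 falls from 5.45 at 0 min to -0.51 at 20 min, while YOR248W climbs from -3.58 to -0.65.

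Several amino acid genes were among the 10 highest against the reference over the whole course, and 5 Ty open reading frames among the 10 lowest. Of 6063 genes, 111 were higher and 195 lower by more than 1.5-fold. The arginine gene ARG1 was higher by 2.75 ± 0.09 (SE, adjusted p = 1.58e-15), the histidine gene HIS4 by 2.60 ± 0.05, ARG7 by 1.89 ± 0.10, ARG4 by 1.87 ± 0.08 and the lysine gene LYS1 by 1.79 ± 0.04. Also among the 10 highest were the Ty3 retrotransposon reading frames YIL080W (3.32 ± 0.07) and YIL082W-A (2.55 ± 0.22), ARO5 (2.59 ± 0.07), the riboflavin gene RIB5 (1.89 ± 0.07) and the mitochondrial carrier GGC1 (1.75 ± 0.04). The 10 lowest were BSC1 (-3.90 ± 0.12), YDL038C (-3.51 ± 0.11), PRM7 (-3.09 ± 0.09), the unfolded protein response factor HAC1 (-3.20 ± 0.27), the phosphate transporter PHO89 (-2.54 ± 0.10) and 5 near-identical Ty open reading frames from -2.60 to -2.47. BSC1, YDL038C and PRM7 are neighbours, and the table of assembly R64 lists YDL038C as a synonym of PRM7. PHO89 was at -3.81 in array set 1 and -1.27 in array set 2.

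In the SIC1 cluster 7 of 19 genes were lower and 0 higher (8 and 1 adjusted over the list alone), led by DSE2 (-2.22 ± 0.25), EGT2 (-1.82 ± 0.11), SCW11 (-1.65 ± 0.19) and DSE1 (-1.54 ± 0.18). Its camera adjusted p of 0.000991 was lost with an estimated correlation (adjusted p = 0.468). The median of its periodic members lay below their own means from 0 to 60 min. The course starts from an arrest and the reference is asynchronous, so these means mix the phases covered with any effect of the deletion. The methionine list had 2 of 11 higher, MET28 (0.96 ± 0.07) and MUP1 (0.84 ± 0.05), and 4 adjusted over the list alone; ribosome biogenesis had 2 of 15 lower, NOG1 (-0.91 ± 0.05) and NSR1 (-0.88 ± 0.05), and 6 adjusted over the list alone. The array sets differed for MUP1 (1.30 in set 1 and 0.39 in set 2) and NSR1 (-1.25 and -0.51). Ribosomal proteins had RPS28B higher and RPP2A lower of 137 (1 and 1 adjusted over the list alone). These 3 lists passed camera, with adjusted p-values of 0.000123, 2.84e-05 and 0.000640, and were lost with an estimated correlation (adjusted p = 0.436, 0.436 and 0.587). Respiration had CIT1 (1.45 ± 0.06) and CYC1 (0.99 ± 0.06) higher of 14, and the stress list HSP104 (1.04 ± 0.04) of 16. In the ECB list MCM5 was higher (0.85 ± 0.05) and FAR1 lower (-1.26 ± 0.14), and CDC6 had a mean of 0.83 ± 0.10 that did not pass (adjusted p = 0.120). The strain markers HIS3 (1.33 ± 0.04) and LYS2 (1.16 ± 0.04) were higher and BAR1 (-1.47 ± 0.21) and HO (-1.24 ± 0.09) lower, while LEU2 was at 1.12 in array set 1 and 0.06 in array set 2. Single genes were lower in the CLB2 cluster (CLB1), the SBF list (YOX1), the pheromone list (BAR1) and the phosphate list (PHO89). The calls of CLB1 and BAR1 were lost without 25, 40 and 55 min (adjusted p = 0.0754 and 0.0139), and CLB1 was at -1.32 in array set 1 and -0.47 in array set 2. The MBF, histone, S/G2 and alpha-cell lists had 0 calls by limma. Without 25, 40 and 55 min, 127 genes were higher and 202 lower, including 104 and 171 of those called. The methionine list then had 5 higher, respiration 4 higher, ribosome biogenesis 3 lower and the phosphate list 2 lower. Array set 1 alone gave 221 higher and 385 lower genes and array set 2 alone 66 and 106. Dye bias of a gene is part of each mean, and for cell cycle genes so are the phases that the course covered.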

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

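The tests without 25, 40 and 55 min, with limit values kept, with 2 harmonics at release and of release against 70, 75 and 80 min were chosen after the data were seen. In the settings below the cause of a change was not tested, except where fewer arrays, genes or a stricter threshold make it. Periodic genes, 805 in number, became 1213 with arrays scaled to the same spread, 508 with 2 harmonics and 1526 without 25, 40 and 55 min. They became 1443 and 324 at adjusted p under 0.05 and 0.001, and 206 with a peak-to-trough size of 1 or more. Within 3 of the 4 title dates with 8 or more time points they were 29, 223 and 0. The other date gave 549, of which 296 were among the 805. The release counts, 80 higher and 77 lower, ranged from 45 to 123 and from 34 to 147 when an array set or a time point was left out; the extremes by time point came without 5 and 15 min for the higher and without 5 and 10 min for the lower genes. The lower count was 45 with scaled arrays, 116 with a period 5 min longer and 41 against 70, 75 and 80 min; both counts were 221 and 244 without 25, 40 and 55 min, 46 and 47 with 2 harmonics, 183 and 179 at adjusted p under 0.05 and 29 and 18 under 0.001. Against the reference, 111 higher and 195 lower genes became 66 to 221 and 106 to 385 with 1 array set left out, 26 and 40 at a fold change of 2, and 1975 and 2003 with no fold change. The mean of YOX1, -1.12, did not pass at a fold change of 2. With an estimated correlation, camera called 1 list in place of 8 at release and 0 in place of 4 for the mean. The period of 71 min became 74, 72, 72, 69 and 70 min without the MBF, SBF, histone, CLB2 and SIC1 markers. The ratio of second to first cycle, 0.567, was 0.567 to 0.575 for single array sets, 0.767 with scaled arrays, 0.579 without the array of conflicting labels, 0.577 without 25, 40 and 55 min and 0.614 without 0 and 5 min. Values not centred gave 135 higher and 171 lower genes for the mean. In all, 3644 comparisons were made of 231 single-gene results, and of the camera results of the lists, with 22 settings. Of these, 3345 stayed on their side of the threshold, 144 lost and 155 gained a call, and 0 changed direction while called. The single genes were those of the naming rule, which favours large effects, so other calls may be less stable. With all 50 arrays, array set as a fixed effect and time point as a random block, 891 genes were periodic, 105 and 113 were called at release and 128 and 218 for the mean. Signal over background is not known here, so ratios of dim spots cannot be told from those of bright ones.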

Other observations

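The 3 lists and the examples named here, and the tests of the samples apart, of the offset, of compressed later arrays and of other choices of 3 time points, were chosen only after the results were seen. The shuffled orders and the ratio without 0 and 5 min were planned before. Predictions on hybridisation faults and probe bias were written after these or related values were known. Amino acid synthesis genes known as Gcn4 targets stood together above the reference: 23 of 40 were higher and 0 lower, with a median of 0.91, and 24 and 0 adjusted over the list alone. Examples beyond those of the report are GCV2 (1.74 ± 0.05), HIS5 (1.46 ± 0.07) and LYS12 (1.25 ± 0.03). Camera gave an adjusted p of 7.06e-16, lost with an estimated correlation (adjusted p = 0.0841). The list holds ARG1, HIS4, ARG7, ARG4 and LYS1, already seen among the highest genes, so these values partly restate that observation. Of 18 Ty open reading frames 9 were lower, all near-identical copies whose probes may overlap, so they count as few independent measurements, while the other 9 lay between 0.02 and 0.24; the list leaves out the Ty3 frames YIL080W (3.32) and YIL082W-A (2.55), which were high (camera adjusted p = 0.0497, and adjusted p = 0.602 with an estimated correlation). Of 13 iron uptake genes 2 were lower at release (5 adjusted over the list alone; median -0.52), with a camera adjusted p of 2.39e-07 and adjusted p = 0.0112 with an estimated correlation; the list was written after FIT2 had been seen, and FIT2 was only -0.71 against 70, 75 and 80 min.

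The deviation of the 25, 40 and 55 min samples from those 5 min before and after correlated across 4494 genes with r = 0.889 between the array sets, which argues against faults of single hybridisations, since the sets lie on different dates; taken singly the r was 0.709 to 0.823, and other times, some of them neighbours of these, gave -0.0467 to 0.807 with a median of 0.379. The deviation was lower for genes of greater coding length (Spearman rho = -0.356 over 5457 genes; -0.343 without ribosomal protein genes), as a bias against long transcripts in these RNA samples may give, though the deviation at 85 min had a rho of -0.430. The deviation at 25 and 40 min recurred at 95 and 110 min, about 1 period later, with r = 0.335, but the pair 70 and 85 min, off that phase, gave 0.481. In array set 2 the 85 min array missed 588 values and had an SD of 0.54, against 0.42 and 0.44 at 80 and 90 min. With the length rho at 85 min given above, that pair is not a clean comparison for phase. The r of 0.335 met the prediction written for a cell cycle cause. The other pairs were looked at only afterwards, and the cause is therefore left open. At these times the median deviation was -1.17 for respiration genes (1 of 14 above 0), -1.05 for ribosome biogenesis (3 of 15) and -0.705 for stress genes (3 of 15). Ribosomal protein genes lay higher by a median of 0.61 (91 of 134 above 0).

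Of 6058 genes, 66 differed between the array sets by more than 1 on the log2 scale; GIT1 was at -3.61 in set 1 and 0.10 in set 2, with a profile r of 0.914 between them. A single hybridisation date is argued against, since offsets over 20 to 55 min and 60 to 115 min, on different dates, correlated with r = 0.695. Compressed ratios in one set stay open, with r = 0.468 between offset and mean ratio. Probe bias of the slides was tested on lists without the 30 largest offsets, which took out 4 of 23 measured heat shock factor genes and 6 of 16 inositol and phospholipid genes. The other heat shock factor genes lay at percentile 26.4 of 10000 random lists, the range predicted for probe bias. Taking out the members with large offsets pulls a list towards random ones, so this value cannot decide on probe bias. The other inositol and phospholipid genes lay at percentile 0.3 (9 of 10 below 0), outside the range predicted for probe bias. Their shared direction thus extended beyond the largest offsets. The list was chosen after the offsets were seen, and that value was seen before its prediction was written, so it does not exclude probe bias. A candidate explanation for the inositol genes is reference RNA that differed between the sets; it was not tested on its own.

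The second cycle was smaller than the first. Carry-over of the arrest is argued against as the whole cause, since the ratio was 0.614 without 0 and 5 min. Compressed ratios of the later arrays stay open: their slope on the means of 243 non-periodic genes was 0.856 of that of earlier arrays. Loss of synchrony was not tested, and ratios over 1 are not covered by these explanations. For the SIC1 cluster such a ratio does not mean a smaller first wave. The centred median of its periodic members lay below 0 from 0 to 60 min and reached 1.78 at 80 min.

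Chance was tested with 100 orders of the time points, the real one included: 1 gave as many as 805 periodic genes, and the highest other order gave 0. Shuffling removes slow drifts too, so these are not excluded. For release, 1 of 100 choices of 3 time points gave as many as 157 genes, the real one, and the highest other gave 12; the times 25, 40 and 55 min, not among those drawn, gave 3179, which points to a structure of these samples.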
